A study of Mus musculus with 6 samples.

How the data were processed

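Single epithelial cells of the mouse small intestine were measured by MARS-seq, a plate-based method in which sorted cells are lysed in wells and each mRNA molecule receives a unique molecular identifier (UMI) at its 3' end. Per the labels' protocols, the small intestine of 120-day-old mice of mixed CD-1 and C57BL/6 background was divided into 12 equal pieces, the third taken as anterior jejunum and the 7th as posterior jejunum, villus and crypt cells were mixed in equal numbers, and EpCAM-positive, DAPI-negative cells were sorted. Each of 3 mice gave 1 anterior and 1 posterior sample, so the 6 samples form 2 groups of 3. The labels give no genotype, and no genotype was assigned. As counted here, each plate held cells of 1 mouse and 1 region. The plate label p06 occurs in posterior mouse 1 and in posterior mouse 2, and was counted as 1 plate in each. Posterior mouse 2 alone had 372 single-cell wells, as many as each other sample with 1 plate. Mouse 1 had 2 anterior and 3 posterior plates and each other sample 1, so for mice 2 and 3 plate and sample cannot be told apart.

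Per the submitters' processing notes, the tools named are bcl2fastq (no version), UMI-tools 1.0.0, cutadapt 1.18, STAR 2.6.1b and R 3.5.1, with the GRCm38/mm10 genome. The deposited values are on a log2 scale: for each region the authors deposited 1 table of genes by cells, and the tables were made separately. How genes and cells were filtered before deposit is not given in the sources used here. Of the anterior values 82.9% stood for 0 UMIs and 35.8% were below 0, against 83.6% and 31.4% of the posterior ones, so the values are corrected log values and not counts. Tested on the values, each deposited value was log2(UMI count/size factor + 1) with a linear correction per gene, which equalised the means of the amplification pools within a region and removed 2 continuous covariates. Undoing this gave whole UMI counts for 100.0% of the values in both tables at a tolerance of 0.01, whereas base e gave 0.395% and 0.928% and base 10 gave 13.5% and 13.1%. On simulated tables of 3000 genes the same procedure returned 100.0% of the counts. All levels below are recovered UMIs per 10000 UMIs of the cell (CP10K), so that the separate scaling of the region tables cancels. The number of columns that could not be mapped to a sample was 0.

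The recovered tables held 2043 cells and 6839 anterior and 5831 posterior genes, of which 5674 were shared (5671 with a symbol) and held 98.0% of the UMIs. Between regions only shared genes were used and totals were taken over them. Within a region the contrast of cell classes used all genes of that table, so levels in those paragraphs differ slightly. Gene positions are from the GENCODE vM21 annotation of GRCm38. No doublet caller was run because cells were sorted singly into wells; wells meant to hold 0 cells (72) or 10 cells (36) were not used here.

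Cells of both tables were clustered together on 1500 variable genes (25 principal components, 15 neighbours, Leiden at resolution 1, which gave 12 clusters). Genes of the 3 held-out lists (ID and E proteins, enteroendocrine transcription factors, gut hormones), 9 of them in both tables, did not enter the clustering or the naming. A cluster was called enterocyte-like, goblet-like, Paneth-like, tuft-like, enteroendocrine-like, stem-like or transit amplifying-like, or T cell-, B or plasma cell-, myeloid- or stromal-like, from 11 marker lists. The highest median log2 ratio to the median cluster (pseudocount 0.5 CP10K) named it if at least 3 markers had a log2 ratio above 1. Stem-like and transit amplifying-like clusters were joined as crypt progenitor-like. A cluster that had over 50% of the markers of at least 2 other classes raised stayed unnamed. This was 1 of 3 naming rules tried and was chosen after the clusters were seen: without it 1 cluster gets another name (Paneth-like), and scoring against the mean of the other cells changes the names of 3. Cluster 6 then becomes Paneth-like, and clusters 5 (enterocyte-like here) and 12 (crypt progenitor-like here) lose their names. Cluster 5 held 163 of the enterocyte-like cells of mouse 1, and the 33 cells of cluster 12 all came from mouse 1. No cluster was named T cell-, B or plasma cell-, myeloid- or stromal-like. Of 13, 8, 8 and 10 markers, 1 (Cd8a), 0, 0 and 1 (Pecam1) were in both tables. Markers listed in 1 table only were also scored, in the cells of that table, and their number is not given here. With so few shared markers, the lack of such names does not show that these cells were absent.

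Shares of cells were compared with a two-sided exact permutation test over samples, which for 3 against 3 cannot go below 0.1, and with Wilson 95% intervals for single samples, which cover counting error only. For genes, mean CP10K per class and sample was taken as log2(mean + 0.2) and tested with limma (eBayes with trend), anterior minus posterior, for genes with a mean of at least 0.2 CP10K. Fold changes are on this scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg over genes. A class needed 5 cells in every sample. Enteroendocrine-like cells were also contrasted with the mean of the enterocyte-like, crypt progenitor-like and goblet-like classes of the same region (the other classes below), with the sample as a block. Gene lists fixed beforehand (23 besides the marker lists) were tested two-sided with camera at the preset correlation of 0.01, adjusted over the lists of a class, where at least 4 members were measured. Besides the held-out lists these were proximal enterocyte genes, distal enterocyte genes, regional transcription factors, fat absorption, carbohydrate digestion and uptake, peptide digestion and uptake, bile acid and cobalamin handling, iron, calcium and folate uptake, retinoid metabolism, xenobiotic metabolism, antimicrobial proteins, MHC class II, cholesterol synthesis, ketone and fatty acid oxidation, the circadian clock, BMP and Notch response, lower villus enterocyte, villus tip enterocyte, dissociation stress and proliferation.

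The groups, tests, lists, markers and most of the other settings tried were chosen before the data were examined. Genes were named by a rule fixed then. In each region comparison these were the 8 largest changes in each direction among genes with adjusted p under 0.05 and no overlap between the samples, or, where none passed, the 3 smallest p in each direction. Up to 4 members of each described list with the smallest p, and Id1, Id2, Id3 and Id4, were added. For the enteroendocrine contrast they were Id1 to Id4, Tcf3, Tcf4, Tcf12 and up to 8 members of each other held-out list. Other genes are said to be chosen after their values were seen. Not every gene that the rule takes is reported here. Several alternatives were chosen after seeing the data: a 3-cell minimum for enteroendocrine-like cells, since 1 posterior sample held 3, keeping the mixed cluster as Paneth-like, the other naming rules, leaving both samples of mouse 1 out, leaving samples out of the list tests, and applying the settings of the enteroendocrine contrast to its count of all genes. Settings chosen beforehand were the mouse as replicate block, other pseudocounts (0.05 and 1), filters, scalings, summed UMIs, means of the deposited values, other clusterings, and leaving out each sample.

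Same-numbered samples are pairs because the labels give them as the same mouse. The correlation of their deviations from the region means was 0.118 to 0.583 over the 3 pairs in enterocyte-like, 0.0485 to 0.272 in progenitor-like, 0.0541 to 0.276 in goblet-like and 0.0356 to 0.256 in enteroendocrine-like profiles. In each class the highest correlation was that of mouse 1. Anterior mouse 2 in progenitor-, goblet- and enteroendocrine-like profiles, and anterior mouse 3 in enteroendocrine-like ones, correlated more with another mouse. Samples of 1 region differed by more than sampling noise, with chi-square per degree of freedom of 15.1 to 122 over genes with at least 10 counts, so none was a copy of another. In simulated profiles with 200 changed genes, limma without a block found 0% of changes of log2 2 in enterocyte-like profiles (4972 genes), 2.02% in progenitor-like (4814), 0% in goblet-like (4292) and 0% in enteroendocrine-like ones (4472). With the mouse as block the shares were 95.0%, 56.6%, 23.0% and 0%, and at log2 1 they were 31.0%, 6.19%, 3.03% and 0%. The simulation gave both samples of a mouse the same base profile, with an assumed noise per sample of 0.2 on the natural log scale. That setting favours the block, so these shares need not hold for the measured samples. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.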

Results

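Single-cell RNA sequencing was performed on the epithelium of anterior and posterior jejunum from 3 mice at 120 days of age, and both regions were sampled in each mouse. The title of the series concerns ID2, an inhibitor of basic helix-loop-helix transcription factors, in the differentiation of hormone-secreting enteroendocrine cells. The design therefore asks which cell classes were present in each region, where Id2 was expressed among them, and which genes differed between the regions. The values hold 2043 cells, 1028 anterior and 1015 posterior, from 3348 wells sorted with a single cell. Anterior samples held 568, 198 and 262 cells with 2887877, 1767832 and 2019506 UMIs, and posterior samples held 511, 280 and 224 cells with 3157105, 1640578 and 1775760 UMIs (mice 1, 2 and 3). The median UMI count per cell was 3051, 8689.5 and 3505.5 in the anterior and 2766, 3417 and 7512 in the posterior samples. Over all cells it was 3468, with a median of 803 genes per cell.

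Clustering gave 12 clusters. Clusters 2, 3, 5 and 7 were enterocyte-like (895 cells, 43.8%) with Apoa1, Apoa4, Fabp1, Reg1 or Reg3g among their leading genes. Cluster 2, led by Malat1 and Apoa4, also had over 50% of the Paneth markers raised. Clusters 1, 9 and 10 were goblet-like (625 cells, 30.6%), led by Muc2, Fcgbp, Zg16 and Clca1. Clusters 4 and 12 were crypt progenitor-like (219 cells, 10.7%), led by Clca3b, Dmbt1 and Hmgb2. Cluster 8 was enteroendocrine-like (117 cells, 5.73%), led by Chgb, Chga and Reg4, and cluster 11 was tuft-like (41 cells, 2.01%), led by Sh2d6. Cluster 6 (146 cells, 7.15%) had 11 of 11 Paneth markers raised together with enterocyte, goblet and enteroendocrine markers, at a median of 885.5 UMIs per cell, and was left unnamed.

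The shares of enterocyte-like and goblet-like cells varied more between the mice of a region than their means differed between regions. Enterocyte-like cells, the absorptive cells of the villus, made up 49.5% ± 24.8 (SD, n = 3) of anterior and 57.4% ± 34.5 of posterior cells, and goblet-like cells, which secrete mucus, 22.9% ± 17.4 and 24.4% ± 26.0. Crypt progenitor-like cells made up 11.9% ± 2.33 of anterior and 7.56% ± 4.08 of posterior cells and were the larger share in the anterior sample of each of the 3 mice. Enteroendocrine-like cells were 5.63% ± 4.36 and 3.49% ± 2.52, again higher anteriorly in 3 of 3 mice, and tuft-like cells 1.66% ± 0.240 and 1.97% ± 1.50. The unnamed cluster held 8.41% ± 0.978 of anterior and 5.15% ± 1.76 of posterior cells, also higher anteriorly in 3 of 3 mice. The equal mixing of villus and crypt cells and the EpCAM gate set part of these shares. None of the 6 shares differed by the two-sided exact permutation test, whose smallest possible p is 0.1 for 3 against 3. Exact p was 0.6 for enterocyte-like, 0.3 for progenitor-like, 0.9 for goblet-like, 0.6 for enteroendocrine-like, 0.7 for tuft-like and 0.1 for unnamed cells (adjusted 0.84, 0.84, 0.9, 0.84, 0.84 and 0.6). An exact sign-flip test over the 3 pairs, whose smallest possible p is 0.25, called no share either (adjusted p at least 0.5). Within pairs, the share was higher anteriorly in 1 of 3 mice for enterocyte-like, goblet-like and tuft-like cells, so there the mice disagreed. Leaving out 1 sample breaks the pair of its mouse, so a turned sign by itself need not mean that the mice disagreed. Leaving out 1 sample turned the sign of the anterior minus posterior difference (in percentage points) for 4 classes. For enterocyte-like cells it was 6.31 without anterior mouse 1, 2.53 without posterior mouse 2 and 1.60 without posterior mouse 3, against −7.88 with all samples. For goblet-like cells it was 1.82 without anterior mouse 2, 4.94 without anterior mouse 3 and 13.4 without posterior mouse 1, against −1.55. It was −0.321 for enteroendocrine-like cells without anterior mouse 1, against 2.15, and 0.365 for tuft-like cells without posterior mouse 1, against −0.313.

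**Figure D1:**
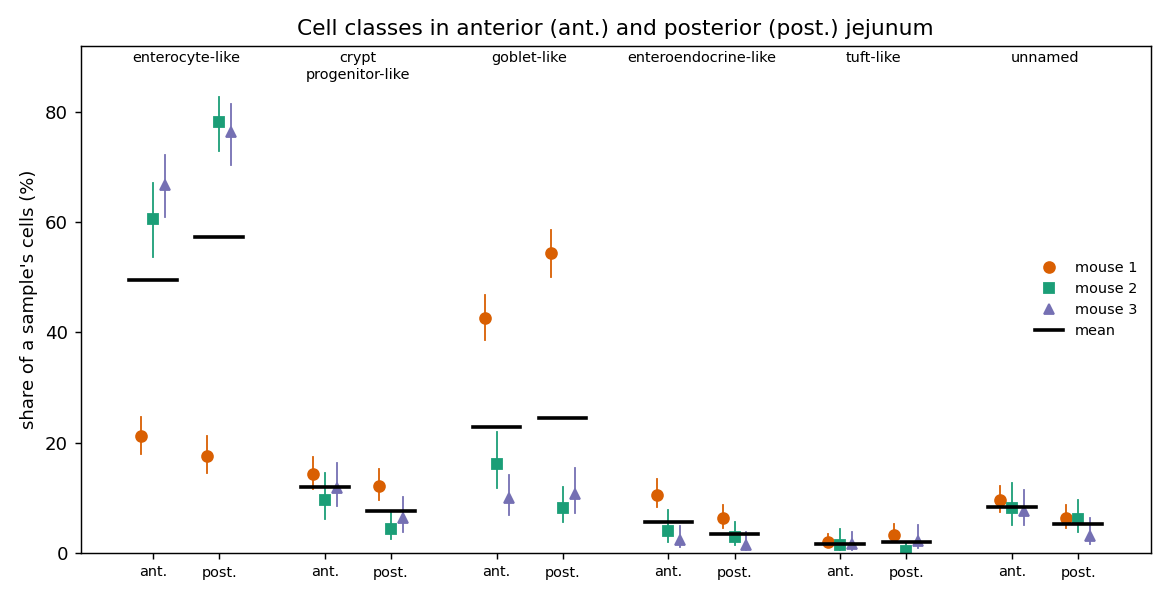
Share of each sample's cells (%) in each cell class, anterior and posterior jejunum, for mice 1 to 3; bars through the points are Wilson 95% intervals and lines are the mean of 3 samples. Mouse 1 had 42.6% and 54.4% goblet-like cells, whereas mice 2 and 3 ranged from 8.21% to 16.2%.

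In the anterior jejunum Id2 was significantly higher in enteroendocrine-like cells compared with enterocyte-like, progenitor-like and goblet-like cells. Id2 (ENSMUSG00000020644, minus strand of chromosome 12, 25093799 to 25097140, GRCm38) reached 4.83 ± 0.580 CP10K (SD, n = 3) in enteroendocrine-like cells, against 0.584 ± 0.243 in enterocyte-like, 0.714 ± 0.135 in progenitor-like and 0.650 ± 0.405 in goblet-like cells. The log2 change against the mean of the 3 tested classes was 2.62 (SE 0.41, limma adjusted p = 1.56e-04), and Id2 was also higher than in each of these 3 classes alone: by 2.72 against enterocyte-like (adjusted p = 6.00e-04), 2.47 against progenitor-like (adjusted p = 0.00123) and 2.67 against goblet-like cells (adjusted p = 0.00110). Without anterior mouse 1 the Id2 adjusted p was 0.0355, and Id2 passed in each of the 3 fits that left out a sample. The related inhibitors Id1 (chromosome 2, 152736251 to 152737410) and Id3 (chromosome 4, 136143497 to 136145755) were also higher in enteroendocrine-like cells. Id1 had 5.03 ± 0.951 CP10K against 1.41 ± 0.323 in enterocyte-like cells (log2 1.16 over the mean of the other classes, adjusted p = 0.0287), and Id3 had 7.34 ± 4.22 against 1.60 ± 0.418 (log2 1.36, adjusted p = 0.0329). Taken class by class, Id1 and Id3 exceeded enterocyte-like cells (adjusted p = 0.00511 and 0.0101) but not progenitor-like (0.305 and 0.0664) or goblet-like cells (0.0656 and 0.249). Neither call was stable: the Id1 adjusted p was 0.113, 0.148 and 0.0899 without anterior mouse 1, 2 or 3, and that of Id3 was 0.205 without mouse 1 and 0.216 without mouse 3. Tcf3 and Tcf12 encode E proteins, the partners that ID proteins bind. Tcf12 (log2 −0.40, adjusted p = 0.279) and Tcf3 (log2 0.27, adjusted p = 0.732) did not pass over the mean of the other classes, and Tcf12 was lower than in progenitor-like cells (log2 −0.85, adjusted p = 0.0490). Of the 5 measured ID and E protein genes 3 passed, and 3 passed when adjusted over the list alone. The count was 1 without mouse 1, 2 without mouse 2 and 1 without mouse 3. Id4 was listed in neither table.

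Hormone genes, which took no part in clustering or naming, were higher in anterior enteroendocrine-like cells in 8 of 8 cases (8 adjusted over the list alone). Secretin (Sct; chromosome 7, 141278330 to 141279133) reached 299.9 ± 71.3 CP10K (log2 change 6.97, adjusted p = 4.00e-14), and ghrelin (Ghrl) 54.7 ± 24.5 (6.92, adjusted p = 7.27e-11). Somatostatin (Sst) stood at 507.1 ± 382 CP10K (log2 6.29, adjusted p = 1.78e-10). Tph1, the enzyme of serotonin synthesis, reached 26.3 ± 11.1 (6.18, adjusted p = 2.08e-10), and Tac1, the precursor of substance P, 16.2 ± 14.9 (5.54, adjusted p = 1.84e-08). Cholecystokinin (Cck), neurotensin (Nts) and the incretin Gip rose by log2 4.47, 3.84 and 4.20 (adjusted p = 0.00106, 0.00197 and 0.00330), although none of the 3 had a UMI in the 6 enteroendocrine-like cells of anterior mouse 3. Without mouse 1 those adjusted p were 0.124, 0.114 and 0.163 and the count of the list was 5. Without mouse 2 the Nts and Gip values were 0.0751 and 0.0818 and the count was 6. It was also 6 without the sample as a block, with Cck at adjusted p = 0.0669 and Gip at 0.123. Sox4 (chromosome 13, 28948919 to 28953713), a transcription factor of endocrine progenitors and the single measured member of the enteroendocrine transcription factor list, rose by log2 2.86 (3.13 ± 1.25 CP10K, adjusted p = 6.13e-04, 1 adjusted over the list alone). Over all genes 246 were higher and 457 lower of 6711 tested, but neither the number nor the balance was stable: 102 were higher and 132 lower without anterior mouse 1, 132 and 70 without mouse 2, 146 and 115 without mouse 3, and 226 and 200 with a pseudocount of 1.

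In the posterior jejunum the enteroendocrine-like class held 32, 8 and 3 cells, below the planned minimum, and was contrasted with a 3-cell minimum chosen after the numbers were seen. Of 5762 genes 54 were higher and 53 lower. These counts were 16 and 15 without posterior mouse 1, 8 and 0 without mouse 2 and 16 and 4 without mouse 3, against 94 and 719 with a pseudocount of 0.05 and 164 and 644 with summed UMIs. Id3 was higher, at 13.6 ± 2.00 CP10K against 2.51 ± 0.478 in enterocyte-like cells (log2 2.10, SE 0.41, adjusted p = 0.0153), while Id1 had a log2 change of 1.43 that did not pass (adjusted p = 0.0693) and Tcf3 of −0.30 (adjusted p = 0.835). Id2 averaged 3.64 ± 5.33 CP10K and did not pass (log2 1.70, SE 0.78, adjusted p = 0.160); it was 9.79 in mouse 1, 0.512 in mouse 2 and 0.610 in mouse 3, with a UMI in 11 of 32, 1 of 8 and 1 of 3 cells. Its log2 change was 0.59 without mouse 1 (adjusted p = 0.705), 2.31 without mouse 2 (0.152) and 2.19 without mouse 3 (0.210). The list count was 1 of 4 (2 adjusted over the list alone). Without posterior mouse 1, 2 or 3 the Id3 adjusted p was 0.0618, 0.152 and 0.159 and the list count was 0, with limma; at unadjusted p under 0.05 the posterior contrast with all samples held 1690 genes. Among hormones 3 of 5 were higher (4 adjusted over the list alone): Sct at 512.4 ± 193 CP10K (log2 7.31, adjusted p = 1.37e-08), Nts (6.72, adjusted p = 3.02e-05) and Cck (4.97, adjusted p = 0.0149). Pyy, a hormone of the distal gut, had a log2 change of 4.05 (adjusted p = 0.0772) and Gip of 2.15 (adjusted p = 0.245), which was −0.88 without mouse 1. These 5 hormones and the 8 of the anterior contrast are different sets. Ghrl, Sst, Tph1 and Tac1 were tested only there, and Pyy only here. Tests of the list between regions used shared genes and so left out those tested in 1 region only. Without mouse 1 or mouse 2 the hormone count was 2, with Cck at adjusted p = 0.110 and 0.152, and without mouse 3 it was 4, with Pyy at log2 7.58. Sox4 rose by log2 2.74 (adjusted p = 0.0359, 1 of 1 in its list and 1 adjusted over the list alone), and its adjusted p was 0.116 without mouse 1 and 0.152 without mouse 2.

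Whether the contrast itself differed between regions was tested directly on 5657 genes. For Id2 the anterior contrast exceeded the posterior by log2 0.90 (adjusted p = 0.710), so a regional difference of Id2 was not shown, and Id1 (−0.08, adjusted p = 0.961), Id3 (−0.68, adjusted p = 0.643), Sct (−0.34, adjusted p = 0.818), Nts (−2.91, adjusted p = 0.257), Cck (−0.58, adjusted p = 0.904) and Gip (2.13, adjusted p = 0.632) did not pass either. In 10 genes the contrast was larger anteriorly, by log2 2.38 to 3.80 (adjusted p = 0.0214 to 0.0458), and in 0 it was larger posteriorly. With limma 0 genes passed in either direction without any 1 of the anterior samples. Without posterior mouse 1 the contrast was larger anteriorly in 62 and posteriorly in 17 genes. These counts were 10 and 8 without posterior mouse 2, and 0 and 3 without posterior mouse 3. The direction was therefore not stable either. At unadjusted p under 0.05 there were 763 genes with all samples, and 733, 595 and 566 without anterior mouse 1, 2 or 3.

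**Figure D2:**
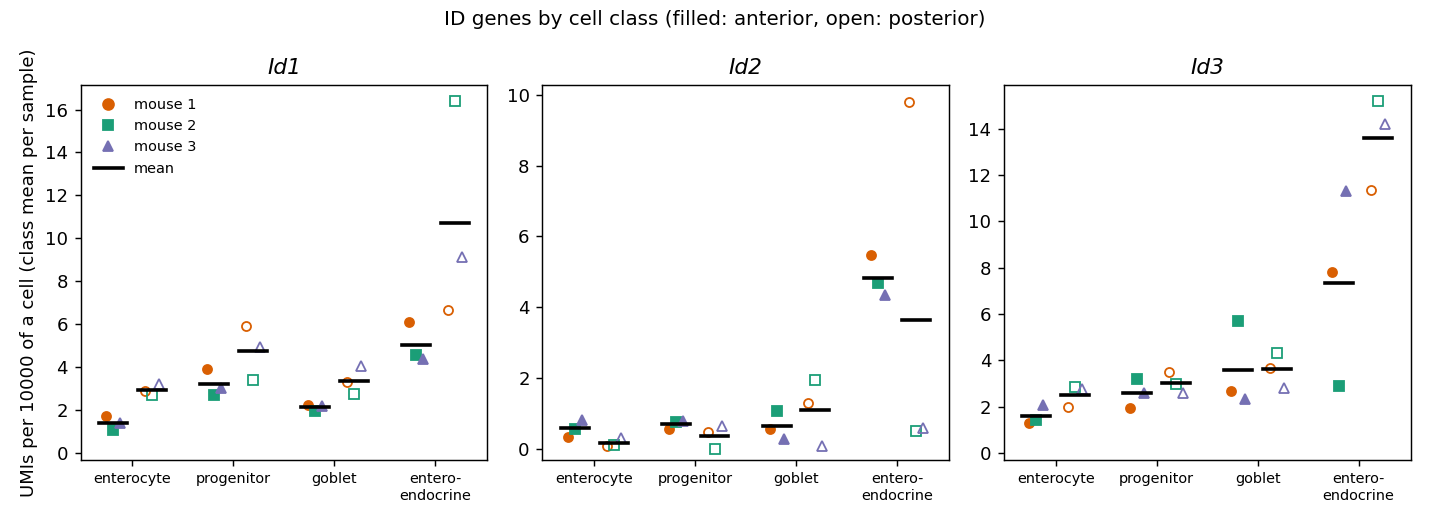
Id1, Id2 and Id3 in 4 cell classes (CP10K); each point is 1 sample, filled for anterior and open for posterior, and lines are means of 3 samples. Id2 in anterior enteroendocrine-like cells averaged 4.83 CP10K, and the posterior samples were spread from 0.512 to 9.79.

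In enterocyte-like cells no single gene passed between regions, but gene lists did. MHC class II genes, which present antigen, were lower in the anterior jejunum: their 7 members summed to 12.2 ± 7.86 CP10K (SD, n = 3) anteriorly and 60.1 ± 26.3 posteriorly, with a median log2 change of −1.94 and 0 of 7 higher anteriorly (camera adjusted p = 8.29e-13). With an estimated correlation the list had adjusted p = 0.277. The invariant chain Cd74 (chromosome 18, 60803848 to 60812652) measured 3.92 ± 2.21 against 26.4 ± 12.9 CP10K (log2 −2.75, adjusted p = 0.509) and H2-Aa (chromosome 17, 34282744 to 34287823) 1.84 ± 1.2 against 10.7 ± 2.76 (log2 −2.61, adjusted p = 0.509). H2-Ab1 was at log2 −2.36 and H2-DMb1 at −1.46. Adjusted over the list alone 5 passed, each of them lower. The T cell marker Cd8a, the single one of 29 T cell, B or plasma cell and myeloid markers in both tables, measured 0.241 ± 0.0945 and 0.221 ± 0.149 CP10K. The secreted lectin Reg1 (ENSMUSG00000059654, chromosome 6, 78422711 to 78428667) measured 48.6 ± 35.5 CP10K anteriorly and 1.75 ± 1.37 posteriorly (log2 4.59, SE 0.80, adjusted p = 0.509). Of 4998 genes limma called 0, with 192 at unadjusted p under 0.05, and 9.42% did not overlap between regions. Chance gives 10% for unpaired samples and less where paired samples resemble each other. With the regions of 1 mouse exchanged, a reference chosen after the values were seen, 4.90% to 6.52% did not overlap. The same exchange called up to 11 lists, against 10 with the real regions, so the number of list calls does not set the real regions apart. The enterocyte-like cells of mouse 1 lay mostly in cluster 5 (84 and 79 of its 120 and 90 cells), those of mice 2 and 3 in clusters 2, 3 and 7. Naming against the mean of other cells leaves cluster 5 unnamed, so the mouse 1 values rest on the naming rule. With both samples of mouse 1 left out, a choice made after its shares were seen, and the mouse as replicate block, limma called 73 genes, 27 higher and 46 lower anteriorly. They included Reg1 (log2 5.62, adjusted p = 8.31e-09), Cd74 (−3.24, adjusted p = 2.31e-07), H2-Aa (−3.00) and H2-Ab1 (−3.02), and 51 of the 73 had the same direction in mouse 1. The share of all genes with the same direction was not determined. With few residual degrees of freedom, these p-values rest largely on the variance that limma shares over genes. With all samples the blocked fit called 0 genes.

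Genes of the proximal enterocyte list rose together in anterior enterocyte-like cells (34 of 38 higher, median log2 0.55, adjusted p = 8.39e-06; 0.277 with an estimated correlation), and those of the distal list fell (4 of 22 higher, median −0.44, adjusted p = 1.96e-06; 0.298 with an estimated correlation). Among distal members the bile acid carrier Fabp6 measured 0.246 against 1.32 CP10K (log2 −1.54). Carbohydrate digestion and uptake rose with 10 of 10 members higher (median 0.57, adjusted p = 2.27e-04; 0.277 with an estimated correlation), among them sucrase-isomaltase Sis (8.87 ± 2.78 against 5.33 ± 1.25 CP10K, log2 0.68), trehalase Treh (log2 0.85) and fructose bisphosphatase Fbp1 (1.16 ± 0.0778 against 0.284 ± 0.212, log2 1.58; 1 member passed over the list alone). Xenobiotic metabolism rose (18 of 20, median 0.78, adjusted p = 1.58e-05; 0.298 with an estimated correlation), with Gsta4 at log2 1.51 and Ces1f at 1.94. Antimicrobial proteins rose as a list (10 of 13, median 0.60, adjusted p = 0.0113; 0.277 with an estimated correlation), with Reg1, Reg4 (1.45), Dmbt1 (1.52) and Il18 (0.95) as the members of smallest p and 1 passing over the list alone. Retinoid metabolism rose (8 of 8, median 0.53, adjusted p = 0.0139; 0.277 with an estimated correlation), including the alcohol dehydrogenase Adh1 (chromosome 3, 138260991 to 138290698; 14.4 ± 6.48 against 6.02 ± 3.56 CP10K, log2 1.31) and the retinol-binding protein Rbp2 (75.7 ± 15.4 against 52.5 ± 11.6, log2 0.53). Its call was lost without anterior mouse 1 (adjusted p = 0.127), anterior mouse 2 (0.0502), posterior mouse 2 (0.102) or posterior mouse 3 (0.0755). Of the antimicrobial members, Reg4 ranged from log2 0.473 to 2.28, Dmbt1 from 0.791 to 2.23 and Il18 from 0.581 to 1.45 with 1 sample left out.

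Peptide digestion and uptake fell in anterior enterocyte-like cells (4 of 15 higher, median −0.38, adjusted p = 3.78e-04; 0.298 with an estimated correlation), where the peptidase Naaladl1 measured 2.02 ± 0.454 against 8.84 ± 5.65 CP10K (log2 −1.77), Mep1a had log2 −1.64 and the peptide transporter Slc15a1 −0.98. Bile acid and cobalamin handling fell (2 of 7 higher, median −0.23, adjusted p = 0.0117; 0.277 with an estimated correlation), with the bile acid exporter subunits Slc51b and Slc51a at log2 −0.89 and −0.48 and the cobalamin receptor subunit Amn at −0.23. It was not called without anterior mouse 1 (adjusted p = 0.0654) or posterior mouse 2 (0.102). With 1 sample left out Amn ranged from log2 −0.402 to −0.0281. Dissociation stress genes, immediate early genes induced by tissue handling, also fell (2 of 13 higher, median −0.61, adjusted p = 4.26e-06; 0.277 with an estimated correlation), with Fos at 5.75 ± 1.42 against 11.4 ± 3.84 CP10K (log2 −0.95), Atf3 at log2 −2.08 and 1 member passing over the list alone. Id1 measured 1.45 ± 0.333 against 2.99 ± 0.259 CP10K (log2 −0.97), Id2 0.60 ± 0.248 against 0.169 ± 0.124 (1.12) and Id3 had log2 −0.58, each with an adjusted p of 0.996. The other genes of smallest p were Gramd3 (log2 1.76, adjusted p = 0.767), Ddx17 (1.67, adjusted p = 0.968) and the transcription factor Osr2 (−1.83, adjusted p = 0.509). With the mouse as replicate block ketone and fatty acid oxidation was called too (adjusted p = 0.0323, against 0.133 without; 0.388 with the block and an estimated correlation).

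The 11 remaining enterocyte-like lists did not pass, with adjusted p = 0.475 for ID and E proteins, 0.154 for BMP and Notch response, 0.687 for cholesterol synthesis, 0.977 for the circadian clock, 0.548 for fat absorption, 0.154 for gut hormones, 0.211 for iron, calcium and folate uptake, 0.133 for ketone and fatty acid oxidation, 0.357 for lower villus, 0.121 for villus tip and 0.977 for regional transcription factors. The median and the test had opposite signs for cholesterol synthesis (median log2 0.04, mean 0.01) and regional transcription factors (0.17 and 0.10), both tested toward posterior, and median and mean differed for fat absorption (0.04 and −0.01). Leaving out 1 sample added calls. Iron, calcium and folate uptake passed without anterior mouse 1 (adjusted p = 0.0427), and gut hormones without anterior mouse 3 (0.00538) or posterior mouse 3 (0.0399). Villus tip genes passed without anterior mouse 3 (0.0132) or posterior mouse 1 (9.39e-04), and fat absorption without posterior mouse 1 (0.0487). Ketone and fatty acid oxidation passed without anterior mouse 2 (0.0496), anterior mouse 3 (0.0259) or posterior mouse 1 (9.39e-04).

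**Figure D3:**
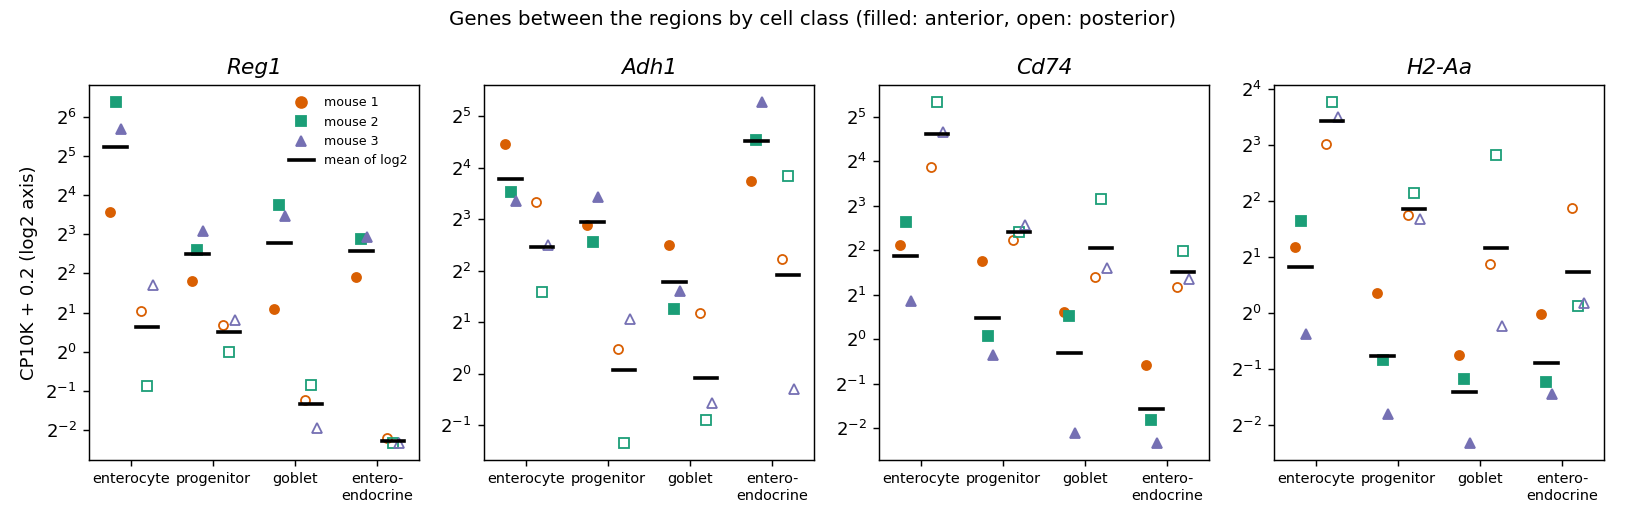
Reg1, Adh1, Cd74 and H2-Aa per sample and cell class (CP10K + 0.2, log2 axis), anterior and posterior jejunum; lines are means of the log2 values of 3 samples. In enterocyte-like cells Reg1 averaged 48.6 CP10K in anterior and 1.75 in posterior samples, and Cd74 3.92 and 26.4.

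In crypt progenitor-like cells part of the same regional lists was called. RNA carried over from enterocyte-like cells was not removed and could supply part of these changes. MHC class II genes were lower anteriorly (1 of 7 higher, median log2 −1.67, adjusted p = 2.23e-09; 0.343 with an estimated correlation; 5 lower adjusted over the list alone), the 7 genes summing to 3.96 ± 3.18 against 14.4 ± 2.87 CP10K (SD, n = 3). H2-Aa measured 0.505 ± 0.510 against 3.45 ± 0.653 CP10K (log2 −2.62, adjusted p = 0.102) and Cd74 1.53 ± 1.42 against 5.10 ± 0.625 (log2 −1.91, adjusted p = 0.415), while Adh1 measured 7.79 ± 2.49 against 1.09 ± 0.850 (log2 2.89, adjusted p = 0.101), Reg1 5.79 ± 2.47 against 1.25 ± 0.404 (2.00, adjusted p = 0.102) and the lectin Reg4 1.52 ± 0.562 against 0.134 ± 0.108 (2.36, adjusted p = 0.102). Lgals3 had log2 −2.03 (adjusted p = 0.415). Of 4875 genes limma called 0 (246 at unadjusted p under 0.05; 9.23% non-overlapping, chance 10% if unpaired, 7.90% to 8.47% with 1 mouse exchanged). With the regions of 1 mouse exchanged, up to 5 lists were called, as many as with the real regions. With the mouse as replicate block limma called 14 genes, 9 higher and 5 lower anteriorly. Those higher were Adh1 (adjusted p = 3.35e-06), Reg1 (0.00120), Reg4 (0.0117), the fatty acid carrier Fabp1 (4.29e-04), Prap1 (0.0145), Dmbt1 (0.0145) and the goblet markers Spink4 (0.00611), Tff3 (0.00185) and Agr2 (0.0481). The lower ones were H2-Aa (7.60e-04), Cd74 (0.00708), the antimicrobial lectins Reg3g (2.16e-07) and Reg3b (0.00185), and the stem marker Clca3b (0.0285). Of these, those not named with values before were chosen after their values were seen. Without a block 3 genes passed without anterior mouse 1 and 1 without posterior mouse 3.

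Progenitor-like cells also had lower distal enterocyte genes (1 of 18 higher, median −0.53, adjusted p = 4.58e-06; 0.325 with an estimated correlation) and lower peptide digestion genes (2 of 13 higher, median −0.57, adjusted p = 6.65e-04; 0.410 with an estimated correlation; 2 lower adjusted over the list alone), such as Naaladl1 (log2 −1.50), Enpep (−1.36) and Dpp4 (−1.08). Retinoid metabolism rose (6 of 8, median 0.57, adjusted p = 0.00763; 0.410 with an estimated correlation; 2 higher adjusted over the list alone), with Adh1 and with Rbp2 at 5.98 ± 0.291 against 2.82 ± 0.346 CP10K (log2 1.04). Xenobiotic metabolism rose (11 of 15, median 0.48, adjusted p = 0.0406; 0.521 with an estimated correlation), with Gstm1 at log2 1.41 and Ces2a at 1.19. Retinoid metabolism was not called without anterior mouse 1 (adjusted p = 0.107) or posterior mouse 2 (0.136), nor xenobiotic metabolism without anterior mouse 1 (0.364), posterior mouse 2 (0.0843) or posterior mouse 3 (0.348). The block added lower villus genes (adjusted p = 0.0176, against 0.134; 0.469 with the block and an estimated correlation), which also passed without anterior mouse 3 (0.0141), and ketone and fatty acid oxidation passed without anterior mouse 1 (0.0172). Other lists did not pass, with adjusted p = 0.610 for ID and E proteins, gut hormones, fat absorption, proliferation and iron, calcium and folate uptake, 0.896 for BMP and Notch response and regional transcription factors, 0.942 for cholesterol synthesis, villus tip and dissociation stress, 0.995 for antimicrobial proteins, 0.299 for bile acid and cobalamin handling, 0.534 for carbohydrate digestion, 0.571 for ketone and fatty acid oxidation and 0.503 for proximal genes. Median and mean differed in sign for BMP and Notch response (−0.11 and 0.06), fat absorption (−0.19 and 0.02), dissociation stress (−0.03 and 0.05) and villus tip (−0.03 and 0.02), and the test opposed both for antimicrobial proteins (−0.14 and −0.03) and cholesterol synthesis (0.02 and 0.04). Id1 measured log2 −0.48, Id2 0.93 and Id3 −0.19 (adjusted p = 0.999).

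In goblet-like cells Reg1 was significantly higher in anterior compared with posterior jejunum, at 8.62 ± 5.92 against 0.214 ± 0.149 CP10K (SD, n = 3; log2 4.10, SE 0.69, limma adjusted p = 0.0128). It was the single gene called of 4249 (132 at unadjusted p under 0.05; 6.75% non-overlapping, chance 10% if unpaired, 5.55% to 6.17% with 1 mouse exchanged). Its call was lost without anterior mouse 2 (adjusted p = 0.541, when 0 genes were called) or anterior mouse 3 (0.289, when another gene passed), and it passed with the mouse as block. Within the anterior samples the goblet-like to enterocyte-like ratio of Reg1 was 0.167, 0.160 and 0.208 in mice 1, 2 and 3, beside a median ratio of 14 enterocyte markers of 0.252, 0.170 and 0.178. A Reg1 UMI was present in 47 of 242, 31 of 32 and 26 of 26 anterior goblet-like cells. Carried-over enterocyte RNA was not removed for the lists that follow. MHC class II genes were lower anteriorly (0 of 5 higher, median log2 −1.93, adjusted p = 4.69e-06; 0.377 with an estimated correlation; 3 lower adjusted over the list alone), with Cd74 at 0.873 ± 0.731 against 4.65 ± 3.52 CP10K (log2 −2.36) and H2-Aa at 0.210 against 3.05 (−2.57). Proximal enterocyte genes rose (31 of 37, median 0.65, adjusted p = 7.22e-05; 0.377 with an estimated correlation), and carbohydrate digestion rose (8 of 9, median 0.66, adjusted p = 0.00516; 0.483 with an estimated correlation), with Tkfc at log2 1.51 and the fructose kinase Khk at 0.73. Xenobiotic metabolism rose (17 of 19, median 0.43, adjusted p = 0.0489; 0.508 with an estimated correlation), with the glutathione transferases Gstm6 (1.15) and Gsta1 (0.95) and Cyp3a25 (−1.03).

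Peptide digestion fell in anterior goblet-like cells (3 of 13 higher, median −0.62, adjusted p = 0.00516; 0.483 with an estimated correlation), with Naaladl1 at log2 −1.71, Enpep at −1.38 and Slc15a1 at −1.28. Dissociation stress fell (3 of 13 higher, median −0.43, adjusted p = 0.00877; 0.508 with an estimated correlation; 1 lower adjusted over the list alone), with Fos at 6.70 ± 4.70 against 17.6 ± 5.06 CP10K (log2 −1.63) and Junb at −1.25. Calls depended on single samples, and the log2 change of Khk ranged from 0.0539 to 1.27 with 1 sample left out. Carbohydrate digestion was lost without anterior mouse 2 (adjusted p = 0.0792), posterior mouse 1 (0.0592) or posterior mouse 3 (0.0901), and peptide digestion without posterior mouse 2 (0.0774) or posterior mouse 3 (0.0901). Dissociation stress was lost without anterior mouse 3 (0.102) or posterior mouse 1 (0.242), and xenobiotic metabolism without anterior mouse 1 (0.245), anterior mouse 2 (0.163), posterior mouse 1 (0.0592) or posterior mouse 3 (0.261). Retinoid metabolism had adjusted p = 0.0544, and 0.0481 with the mouse as block (0.466 with the block and an estimated correlation), and passed without posterior mouse 2 (0.0127). Distal genes had adjusted p = 0.0618 and passed without anterior mouse 2 (0.0266) or posterior mouse 1 (0.0469), and gut hormones (0.320) passed without anterior mouse 3 (1.37e-04). The remaining lists did not pass: ID and E proteins and regional transcription factors (0.340), BMP and Notch response (0.503), cholesterol synthesis, fat absorption and proliferation (0.335), the circadian clock (0.131), iron, calcium and folate uptake (0.373), ketone and fatty acid oxidation (0.233), lower villus (0.343), villus tip and antimicrobial proteins (0.148), and bile acid and cobalamin handling (0.607). Median and mean differed in sign for iron, calcium and folate uptake (−0.00027 and 0.20). Id1 measured 2.20 ± 0.168 against 3.41 ± 0.655 CP10K (log2 −0.58), Id2 had log2 −0.27 and Id3 −0.07 (adjusted p = 0.999).

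Enteroendocrine-like cells, compared between regions with the 3-cell minimum chosen after the cell numbers were seen, had higher Reg4 and Reg1 in the anterior jejunum. Reg4 (chromosome 3, 98222156 to 98236748) reached 508.9 ± 167 against 133 ± 59.1 CP10K (SD, n = 3; log2 1.98, SE 0.29, limma adjusted p = 5.69e-08). Its adjusted p was 0.0646 without posterior mouse 3. Limma without a variance trend called 0 genes in this class, and so did a filter of at least 1 CP10K. Reg4 was therefore lost in both settings. Reg1 had 6.03 ± 2.18 against 0.00562 ± 0.00974 CP10K (adjusted p = 0.0257, and 0.0942 with the mouse as block), and with UMIs in 1 posterior sample its fitted log2 change of 4.85 rests on the pseudocount. Anterior Reg1 averaged 5.79 CP10K in progenitor-like, 8.62 in goblet-like and 6.35 in tuft-like cells, beside 48.6 in enterocyte-like cells. Carried-over enterocyte RNA could supply it here too, and was not removed for Reg1 or the lists of this class. Reg1 was not called without anterior mouse 1 (adjusted p = 0.372), anterior mouse 2 (1.00), anterior mouse 3 (0.999) or posterior mouse 1 (0.199). Nts (chromosome 10, 102481756 to 102490486) was lower, at 28.7 ± 27.7 against 578 ± 817 CP10K (log2 −3.94, adjusted p = 5.69e-08), and Gip (chromosome 11, 96024545 to 96030831) higher, at 543 ± 486 against 87.4 ± 151 (4.53, adjusted p = 5.01e-06), but their samples overlapped and neither passed with the mouse as block (adjusted p = 0.831 and 0.352), although Nts did when both samples of mouse 1 were left out as well (log2 −7.43, adjusted p = 1.27e-79). That fit rests on 2 mice and on a 0 in anterior mouse 3. Mouse 1 went the other way, with 30.9 CP10K anteriorly and 3.58 posteriorly. Gip measured 939, 689 and 0 CP10K in anterior and 262, 0 and 0 in posterior mice 1, 2 and 3. With all samples the p-values of Nts and Gip rest on the variance that limma shares over genes, not on their own spread. Nts was not called without anterior mouse 3 (adjusted p = 0.999), posterior mouse 1 (0.315), posterior mouse 2 (0.0760) or posterior mouse 3 (0.416). Gip was not called without anterior mouse 1 (adjusted p = 0.992), anterior mouse 2 (1.00), posterior mouse 1 (0.528) or posterior mouse 2 (0.788). These 4 genes were the calls among 4556 (159 at unadjusted p under 0.05; 10.3% non-overlapping, chance 10% if unpaired, 6.87% to 7.55% with 1 mouse exchanged), against 2 with the block, Reg4 and Sct (324 ± 79.1 against 546 ± 223 CP10K, log2 −0.69, blocked adjusted p = 0.0359). The count was 2 without anterior mouse 2, 1 without posterior mouse 1 and 3 without each other sample. Id1 measured 6.01 ± 0.785 against 10.9 ± 5.26 CP10K (log2 −0.75), Id2 5.21 ± 0.644 against 3.73 ± 5.37 (1.49) and Id3 7.93 ± 4.48 against 13.7 ± 2.04 (−0.96), each with adjusted p = 0.981.

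Among lists in enteroendocrine-like cells retinoid metabolism rose anteriorly (7 of 8, median 1.57, adjusted p = 0.00555; 0.394 with an estimated correlation; 1 higher adjusted over the list alone), with Adh1 at 24.9 ± 12.7 against 6.42 ± 6.98 CP10K (log2 2.59), the retinol saturase Retsat at 1.73 ± 0.242 against 0.126 ± 0.174 (2.69) and Rbp2 at log2 1.29. Distal enterocyte genes fell (5 of 18 higher, median −0.27, adjusted p = 0.0178; 0.646 with an estimated correlation), and MHC class II fell (2 of 5 higher, median −1.62, adjusted p = 0.0178; 0.635 with an estimated correlation; 2 lower adjusted over the list alone), with Cd74 at log2 −3.08, H2-Ab1 at −2.91 and H2-DMa at 0.96. MHC class II was not called without anterior mouse 3 (adjusted p = 0.125), posterior mouse 1 (0.0535), posterior mouse 2 (0.0671) or posterior mouse 3 (0.105), distal genes not without posterior mouse 1 (0.108) or posterior mouse 2 (0.234), and retinoid metabolism not without posterior mouse 1 (0.0535). Gut hormones (adjusted p = 0.165; median −0.15, mean 0.07) passed toward posterior without anterior mouse 1 (7.12e-06) or anterior mouse 2 (3.34e-09) and toward anterior without anterior mouse 3 (2.50e-05). Not passing were ID and E proteins and peptide digestion (0.546), BMP and Notch response and carbohydrate digestion (0.455), cholesterol synthesis and regional transcription factors (0.618), fat absorption, lower villus and proximal genes (0.236), iron, calcium and folate uptake and dissociation stress (0.238), ketone and fatty acid oxidation and antimicrobial proteins (0.462), xenobiotic metabolism (0.490), villus tip (0.161) and bile acid and cobalamin handling (0.798). Median and mean differed in sign for ID and E proteins (−0.14 and 0.07), cholesterol synthesis (−0.29 and 0.13), fat absorption (0.11 and −0.04) and lower villus (0.14 and −0.17), and the test opposed both for bile acid and cobalamin handling (0.37 and 0.19), peptide digestion (0.20 and 0.07) and regional transcription factors (0.57 and 0.08). The enteroendocrine transcription factor list had under 4 members in every class and was not tested between regions.

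**Figure D4:**
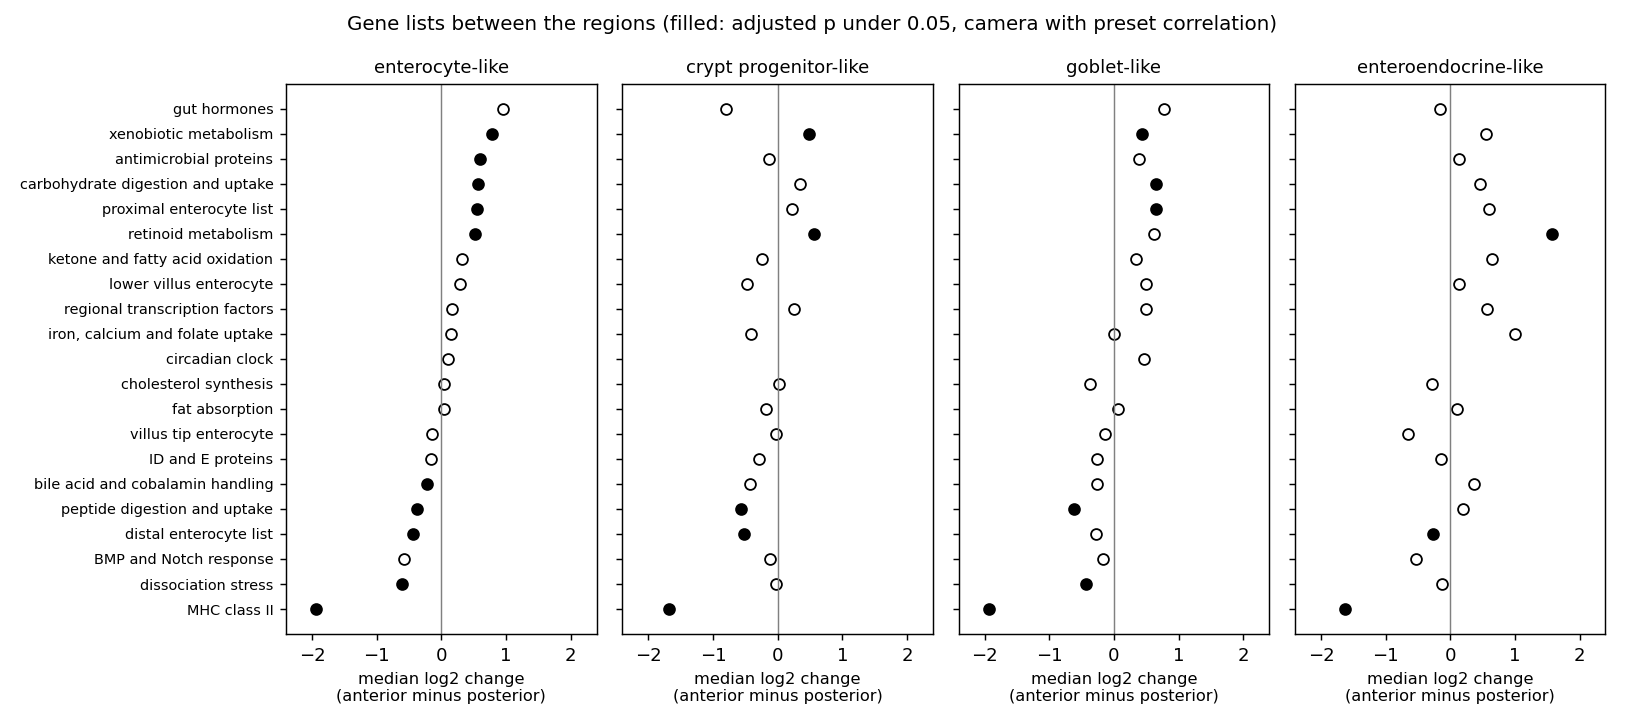
Median log2 change (anterior minus posterior) of 21 gene lists in 4 cell classes; filled points had an adjusted p under 0.05 with camera at the preset correlation, none of which held with an estimated one. MHC class II lay at −1.94 in enterocyte-like, −1.67 in progenitor-like, −1.93 in goblet-like and −1.62 in enteroendocrine-like cells.

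The unnamed cluster, kept as Paneth-like in an alternative chosen after seeing the data, had higher Reg1 anteriorly, at 31.9 ± 20.3 against 0.119 ± 0.207 CP10K (SD, n = 3; log2 6.50, limma adjusted p = 4.26e-04), with UMIs in posterior mouse 1 alone, so that the fitted change rests on the pseudocount. It was the only call among 4098 genes (133 at unadjusted p under 0.05; 8.57% non-overlapping, chance 10% if unpaired, 5.71% to 6.95% with 1 mouse exchanged). The count was 0 without anterior mouse 2 or anterior mouse 3, 3 without posterior mouse 1 and 2 without posterior mouse 2. Enterocyte markers were raised in this cluster, and anterior enterocyte-like cells had 48.6 CP10K of Reg1. Carried-over enterocyte RNA could supply it and was not removed. MHC class II fell as a list (median −2.17, adjusted p = 2.92e-05; 0.160 with an estimated correlation). Carbohydrate digestion rose (median 0.73, adjusted p = 0.0414), but had adjusted p = 0.0597 with the mouse as block and 0.530 with an estimated correlation. The other 19 lists did not pass. Tuft-like cells (11, 3 and 4 anterior, 17, 1 and 5 posterior) were too few to test.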

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

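The splits and the shuffling of cells given here were chosen after the result was seen. The enteroendocrine-like contrast differed between anterior and posterior jejunum for 10 genes by the limma test of the difference itself, and all 10 contrasts were larger anteriorly. The log2 differences were 3.55 for the GTPase Rala, 3.44 for Nosip, 3.55 for Swi5, 3.17 for the protease Ctsz, 3.80 for N4bp2l2, 3.29 for the epithelial transcription factor Hnf4a, 2.38 for the ATP synthase subunit Atp5a1, 2.96 for Pdcd6, 3.05 for the chaperonin subunit Cct2 and 2.79 for the NF-kappaB subunit Rela. Adjusted p ranged from 0.0214 to 0.0458.

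These differences rest on few posterior cells. In posterior enteroendocrine-like cells Rala had 0.204, 0 and 0 CP10K in mice 1, 2 and 3 (32, 8 and 3 cells), against 1.57, 1.96 and 3.26 anteriorly, Rela had 0 in each of the 3, and Atp5a1 had 2.39, 1.00 and 0.610 against 6.66, 10.05 and 7.55. Fitted differences of genes at 0 depend on the pseudocount and are no bounds. The count was 0 without anterior mouse 1, 2 or 3, 79 without posterior mouse 1 (17 larger posteriorly), 18 without posterior mouse 2 (8 larger posteriorly) and 3 without posterior mouse 3 (3 larger posteriorly), so the common direction was not kept. After shuffling the region of enteroendocrine-like cells within each mouse, which removes differences between regions and keeps those between mice, 10 of 100 draws called at least as many genes, up to 27. The 10 splits of the 6 samples are too few for a share under 0.05. In 5 of them, the real one included, at least 10 genes were called, and the highest other count was 54, from a split that keeps both samples of 2 mice together. Whether such a count reflects a structure of the samples by mouse was not tested. Among the splits that part all 3 pairs the highest other count was 5.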

How the results depend on the processing

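The alternatives chosen only after the data were seen were the 3-cell minimum, Paneth-like cells, naming against the mean of other cells, leaving out both mouse 1 samples, leaving samples out of the list tests, and the settings of the count of all genes in the enteroendocrine contrast. Across alternatives, 2876 values of single genes and lists kept their direction and side of the threshold, 158 lost a call, 58 gained one and 28 turned direction. Of the counts and class shares 276 held, 75 moved and 10 turned direction. Id2 in anterior enteroendocrine-like cells passed in 11 of 11 other settings (log2 0.93 to 2.89) and in the posterior in 0 of 11 (adjusted p 0.0581 to 0.208). Where no cause is given, the cause was not tested.

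With the mouse as replicate block, genes called went from 0 to 14 in progenitor-like and from 4 to 2 in enteroendocrine-like cells, where Reg1, Nts and Gip were lost and Sct was gained. Ketone oxidation in enterocyte-like, lower villus in progenitor-like and retinoid metabolism in goblet-like cells were added, carbohydrate digestion in Paneth-like cells was lost (1 list called against 2), and the block changed no other call of a list or count of genes. An estimated correlation left 0 lists in each of the 4 classes and in Paneth-like cells, with or without the replicate block.

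Means of the deposited log values called 1355 genes in enterocyte-like, 49 in progenitor-like, 46 in goblet-like and 0 in enteroendocrine-like cells. This setting does not compare regions soundly, because the authors' correction centred each region's table separately. It turned Fos in enterocyte-like (0.048), Reg4 (−0.026), Lgals3 (0.40), Naaladl1 (0.31) and Id3 (0.19) in progenitor-like, Gstm6 (−0.028) and Id3 (0.068) in goblet-like and Naaladl1 (0.022) in enteroendocrine-like cells. Without both mouse 1 samples and with the block 73 enterocyte-like, 6 progenitor-like, 7 goblet-like, 5 enteroendocrine-like (Reg4, Sct and Fabp2, with the same direction in mouse 1, and Nts and Crip1, with the opposite one) and 2 Paneth-like genes were called. Leaving out both mouse 1 samples without the block left 0 enteroendocrine-like and 0 Paneth-like genes and 0 enteroendocrine-like lists, from fewer samples. Shares then differed by 3.58 percentage points in goblet-like and 0.226 in tuft-like cells, and with or without the block Id3 in progenitor-like (0.095) and Id2 (0.064) and Id3 (0.080) in goblet-like cells turned.

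A pseudocount of 1 called 2 progenitor-like and 1 enteroendocrine-like genes and turned Tcf3 in the posterior contrast (0.17). A pseudocount of 0.05 called 2 enteroendocrine-like and 3 Paneth-like genes and 2 posterior ID and E proteins, as did summed UMIs (2). Without a filter 1 enteroendocrine-like and 0 Paneth-like genes were called. A filter at 1 CP10K left 0 goblet-like and 0 enteroendocrine-like genes, although the genes called in the main fits also passed this filter. Limma without a trend left 0 and 0. Scaling by median ratios left 2 enteroendocrine-like genes, and leaving out the top 2% of cell totals gave 1 progenitor-like gene. Naming against the mean of other cells left 0 posterior enteroendocrine transcription factors. The anterior contrast, with 703 genes called, called 451 without the sample as a block, 426 with a pseudocount of 1 and 1126 with summed UMIs, and the posterior one, with 107, called 813 with a pseudocount of 0.05, 808 with summed UMIs and 61 with naming against the mean of other cells. Without the sample as a block 6 of 8 anterior hormones passed.

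Leaving out each sample gave 0 to 3 genes in progenitor-like, 0 to 1 in goblet-like, 1 to 3 in enteroendocrine-like and 0 to 3 in Paneth-like cells, and 0 to 79 genes whose contrast differed between regions. Lists numbered 3 to 7 in progenitor-like, 3 to 6 in goblet-like and 0 to 6 in enteroendocrine-like cells. Anterior ID and E proteins numbered 1 to 2 and hormones 5 to 8. The contrasts called 202 to 261 genes in the anterior and 8 to 31 in the posterior. In the posterior 0 ID and E proteins, 2 to 4 hormones and 0 to 1 transcription factors passed. Share differences ranged from −27.8 to 6.31 in enterocyte-like, −11.4 to 13.4 in goblet-like, −0.321 to 3.82 in enteroendocrine-like and −1.12 to 0.365 in tuft-like cells. Log2 changes that turned ranged from −0.45 to 0.17 (Id3) and −1.18 to 0.31 (Id2) in goblet-like, −1.68 to 0.35 (Gm26917) in enteroendocrine-like and −2.13 to 0.050 (Id1) in Paneth-like cells, and from −0.15 to 0.48 for Tcf3 in the anterior and −1.71 to 0.57 for Tcf3 and −0.88 to 4.05 for Gip in the posterior contrast. A lone sample left in an arm is assumed to vary like the others. Planned tests of tuft-like cells, and of enteroendocrine-like cells between regions and in the posterior contrast with the 5-cell minimum, and of Paneth-like cells as named, were not run for want of cells. Enteroendocrine-like values rest on as few as 3 cells per sample.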

Other observations

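Other splits of the samples, the shuffling of cells, the fit on mice 2 and 3 alone, the test of free RNA for MHC class II and the comparison of lists between goblet-like and enterocyte-like cells were chosen after the result was seen. Mouse 1 differed in composition from mice 2 and 3 in both regions: its samples held 42.6% and 54.4% goblet-like and 21.1% and 17.6% enterocyte-like cells, whereas the 4 samples of mice 2 and 3 held 8.21% to 16.2% and 60.6% to 78.2%. This was seen in each plate, with 42.1% to 58.9% goblet-like cells in the 5 plates of mouse 1. Most goblet-like cells of mouse 1 lay in cluster 1 (440 cells), where the median was 1912 UMIs per cell. Clusters 9 and 10 held 70 and 10 of its cells and had medians of 9373 and 13500 UMIs. Whether this depth bears on the difference was not tested. Wells were labelled positive or negative for an unnamed cell marker. Tuft-like cells made up 1.39% ± 0.961 (SD, n = 6) of cells in positive and 2.33% ± 1.43 in negative wells, positive higher in 1 of 6 samples (exact sign-flip p = 0.0938, adjusted 0.563), and the other classes had exact p of at least 0.875. Between positive and negative wells limma called 0 of 5005 genes in enterocyte-like cells (273 at unadjusted p under 0.05), 0 of 4869 in progenitor-like (214) and 1 of 4254 in goblet-like cells (162; smallest adjusted p = 0.0046).

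Some genes called in mice 2 and 3 with the mouse as block were not named above. In enterocyte-like cells the folate transporter Slc46a1 (log2 2.11), the ferritin chain Fth1 (1.57) and the sulfate donor enzyme Papss2 (2.74) were higher anteriorly, and the guanylate cyclase ligand Guca2a (−1.89) and the fatty acid carrier Fabp2 (−2.01) lower. Guca2a was lower in goblet-like cells as well (−1.72). These are single genes chosen after their values were seen, and no group was tested. Slc46a1 and Fth1 belong to the iron, calcium and folate uptake list and Fabp2 to the fat absorption list, which did not pass with all samples (adjusted p = 0.211 and 0.548), and 51 of the 73 enterocyte-like calls had the same direction in mouse 1.

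MHC class II transcripts were lower in anterior enterocyte-like cells (12.2 ± 7.86 against 60.1 ± 26.3 summed CP10K). RNA from immune cells shared by all wells would give enterocyte-like and goblet-like cells of a sample about the same level, but the enterocyte-like level was at least 3.56 times the goblet-like one in each of the 3 posterior samples, which argues against it as the whole source. A few immune cells inside the class would hold most of the sum, but the 5% of cells with the most held at most 20.48%, and 89 of 90, 218 of 219 and 170 of 171 cells had a UMI. The EpCAM gate is meant to remove immune cells. Their transcripts could be compared between regions through 1 of 29 markers, Cd8a, at 0.241 ± 0.0945 CP10K anteriorly and 0.221 ± 0.149 posteriorly. A regional difference in the epithelium, or in signals reaching it, may remain as a hypothesis that was not tested here.

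Reg1 was higher in anterior goblet-like cells (8.62 ± 5.92 against 0.214 ± 0.149 CP10K). RNA from enterocyte-like cells could supply it: in anterior mouse 1, 11 of 14 enterocyte markers had a goblet-like to enterocyte-like ratio at or above that of Reg1, and in mice 2 and 3 it was 8 and 5. A few mixed or misnamed cells remain possible too, since the top 5% of goblet-like cells held 74.9% of Reg1 in mouse 1, while in mice 2 and 3 they held 26.7% and 28.7%. Neither was excluded, and a regional difference within goblet cells stays open as untested. Anterior Reg1 in progenitor-like, enteroendocrine-like, tuft-like and Paneth-like cells was not compared with enterocyte markers in this way. Carried-over RNA could supply the changes of gene lists in goblet-like cells as well. MHC class II, proximal genes, carbohydrate digestion, xenobiotic metabolism and peptide digestion had median log2 changes of −1.93, 0.65, 0.66, 0.43 and −0.62 there and, in the same directions, −1.94, 0.55, 0.57, 0.78 and −0.38 in enterocyte-like cells.

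Id2 in posterior enteroendocrine-like cells was 9.79 CP10K in mouse 1, 0.512 in mouse 2 and 0.610 in mouse 3. Few cells could account for the low values: of 100000 random draws of 8 cells from mouse 1, 5.83% had a mean at or under that of mouse 2, and of draws of 3 cells 30.9% had one at or under that of mouse 3. The share for mouse 2 lies just above the 5% set beforehand. The mouse 1 cells had a median of 1368.5 UMIs, against 3812 in mouse 2 and 5468 in mouse 3. The draws did not allow for this depth, and the low values were not tested together. A difference between the mice, or of the region, stays open as untested.

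The 6 samples make 10 splits into 2 groups of 3, too few for a share under 0.05. In enterocyte-like cells 0 genes were called in the real split and 4 at most in another (10 of 10 splits had as many as the real one), in progenitor-like cells 0 and 2 (10 of 10), in goblet-like cells 1 and 4 (2 of 10), in enteroendocrine-like cells 4 and 10 (4 of 10) and in Paneth-like cells 1 and 4 (4 of 10). For lists the real and highest other counts were 10 and 11 in enterocyte-like (2 of 10), 5 and 5 in progenitor-like (2 of 10), 6 and 5 in goblet-like (1 of 10) and 3 and 3 in enteroendocrine-like cells (3 of 10). When the region of enteroendocrine-like cells was shuffled within each mouse, 0 of 100 draws called 4 genes or more, and the highest count was 3. That shuffling treats cells as the unit and so leaves out differences between samples of the same mouse. Gene counts above the real one came only from the 6 splits that keep both samples of 2 mice together. Not all of those splits gave such counts, and whether they reflect a structure of the samples by mouse was not tested. The 4 splits that part all pairs, the real one included, had at most 0, 0, 0, 4 and 0 genes in the other 3. With the mouse as block the real split called 14 progenitor-like genes and the other 3 of those 4 at most 0, and 1 against 0 in goblet-like and 2 against 1 in enteroendocrine-like cells. Lists in those 4 splits numbered 10 against 11, 5 against 5, 6 against 3 and 3 against 1.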
